A study of Mus musculus with 8 samples.

How the data were processed

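Total RNA from razor-scraped distal colonic epithelium of 8 mouse samples, 4 control and 4 K-Ras-G12D, was made into poly-A selected, directional libraries, per the labels' protocols. Per the submitters' processing notes, Salmon 0.14.1, DESeq2 and the mouse build mm10, also called GRCm38, were used, with no role or order given. Other settings of the counting are not given in the sources used here. The authors deposited estimated counts per gene and sample, rounded to whole numbers, in a table of 10962 genes. Per the file headers, further tables held normalized values per sample, a non-negative signal, and their mean. That deposited signal was the count divided by a factor for each gene and sample, and it served to derive those factors. The deposited log2 fold changes and their standard errors, the deposited test score and the deposited p-value and adjusted p-value of each gene were the authors' own comparison. The adjusted p-values followed from 14018 genes, so the table is a part of those tested, and its lowest mean was 26.2. Of the 10962 genes, 10938 matched the GENCODE M21 annotation of GRCm38 by identifier, from which coordinates were taken, and 10610 were protein-coding, 275 pseudogenes and 0 lincRNAs. Genes outside the table, such as Xist and Lgr5, were not analysed here. Totals per sample were 14255505 to 17795679 counts over the genes of the table.

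Groups followed the genotype in the labels. The deposited counts entered edgeR 4.0.16 (R 4.3.3) as whole numbers, with the default filter by expression, which removed 18 genes, TMM normalisation, robust dispersions and the quasi-likelihood F-test of genotype with Benjamini-Hochberg adjustment over 10944 genes at a threshold of 0.05. Tests of genes and lists are two-sided. Fold changes are K-Ras-G12D over control. CPM values are counts scaled to the TMM-normalised library size, except the sums of the Y-linked genes, which are scaled to the total count. Standard errors were derived from the fold change and its F statistic. Biological variation had a square root dispersion of 0.286. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A floor of 3 counts over the group was used where all samples of a group were at 0.

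Before the data were examined, 41 gene lists of pathways, epithelial cell types and other cells of a colon scraping were fixed: ERK pathway output, EGFR family ligands, immediate early genes, proliferation, senescence and p53 targets, Wnt, Notch and BMP pathways, YAP and fetal-like genes, antimicrobial defence, interferon response, MHC class II, chemokines, cholesterol synthesis, fatty acid oxidation, glycolysis and hypoxia, oxidative phosphorylation, ribosome biogenesis, unfolded protein response, epithelial-mesenchymal transition, ion transport, circadian clock, stem cells, colonocytes, goblet cells, deep crypt secretory and Paneth cells, enteroendocrine cells, tuft cells, small intestine, and cells of muscle, connective tissue, vessels, blood, immune, neural, squamous and fat origin. The 36 lists with at least 4 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. A list score was the mean over members of log2 CPM (prior count 2) centred per gene. Named genes followed a rule fixed with the lists. It named Kras, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, without unnamed gene models, immune receptor segments and sex-specific genes, and up to 4 members per list with the smallest p that passed, or the 2 most expressed members as values where none passed.

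Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter and a filter of 1 CPM in 4 samples, a test against a log2 fold change of 0.5 (glmTreat), each library left out in turn, the replicate number as a block, and covariates made of the male-specific genes or of stromal markers. The authors' factors as offsets, in edgeR and in DESeq2, and a Hox score as a covariate, alone and with the male-specific covariate, were added after the data were seen. The 8 samples make 35 splits into 4 and 4, and all were tested. The tests were tested on simulated data with the genes' means and library sizes and 200 changed genes, beside the ERK output genes, which were raised 2-fold. Each gene was drawn independently and a smaller share changed than was called in the real data, so the rates below need not hold there. There edgeR recovered 5.97% of the genes changed 1.5-fold, 50.7% of those changed 2-fold and 87.7% of those changed 4-fold, over 10930 genes, with 4.63% of calls false. DESeq2 recovered 23.9%, 65.7% and 97%, with 22.1% of calls false over 10944 genes. Replicates of a group differed by more than sampling noise, so none was treated as a duplicate.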

Results

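Poly-A RNA was sequenced from the scraped epithelium of the distal colon of C57BL/6 mice aged 8 to 12 weeks. The 4 control samples came from mice with the Fabp-Cre transgene and wild-type K-Ras, and the 4 K-Ras-G12D samples from mice that also carried 1 oncogenic K-Ras-G12D allele. Fabp-Cre is a Cre recombinase driven in the gut epithelium, and G12D is a point mutation that keeps the K-Ras GTPase in its active state. The deposited table held estimated read counts for 10962 genes, with 14255505 to 17795679 counts per sample over those genes. These sums cover the genes in the table and not the whole library. Of these genes, 10944 had enough counts to be tested. The labels do not say that each sample came from a separate mouse, so the p-values measure the spread between these samples. The comparison addressed how endogenous expression of K-Ras-G12D changes the transcriptome of the colonic epithelium.

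Colonic epithelium with K-Ras-G12D had higher transcript levels of 12 of 17 ERK pathway target and feedback genes, with 1, Ccnd1, lower, and of 8 of 22 genes of glycolysis and the hypoxia response than control epithelium. These 2 lists rose with a preset correlation between genes, and had an adjusted p of 0.0996 and 0.400 with an estimated correlation. The ERK phosphatase gene Dusp4 rose 9.66-fold and the glucose transporter gene Slc2a1 rose 3.12-fold. Lower were 7 of 21 genes of oxidative phosphorylation, 3 of 8 of deep crypt secretory and Paneth cells and 2 of 14 of antimicrobial defence (adjusted p = 0.502, 0.106 and 0.502 with an estimated correlation). Falls were 42.8-fold for the lectin gene Itln1 and 8.00-fold for Retnlb, a goblet cell product with antimicrobial activity. The Wnt target Axin2 fell 3.86-fold, from 19.0 ± 4.48 to 4.90 ± 1.38 CPM (counts scaled to the normalised library size; mean ± SD, n = 4 per group). Each of these genes passed the edgeR quasi-likelihood test at an adjusted p of 0.05, with values in the groups that did not overlap.

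The engineered gene itself, Kras (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239, GRCm38), was measured at 166.3 ± 15.5 CPM in control and 219.5 ± 31.4 CPM in K-Ras-G12D samples (mean ± SD, n = 4 each). The control samples ran from 152.2 to 188.3 CPM and the K-Ras-G12D samples from 191.3 to 264.2 CPM. The log2 fold change was 0.40 ± 0.12 (SE), with an edgeR adjusted p of 0.0629, which missed the threshold of 0.05. It passed with DESeq2 (log2 fold change 0.42, adjusted p = 0.0150) and without K-Ras-G12D replicate 2 (log2 fold change 0.46, edgeR adjusted p = 0.0467). Kras also passed with the replicate number as a block and with DESeq2 and the authors' factors. A count per gene holds reads of both alleles, so it cannot show the point mutation.

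Of the 10944 genes tested, 1490 (13.6%) differed between the groups, 907 higher and 583 lower in K-Ras-G12D (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of 0.05 or less). Of these, 318 rose and 196 fell at least 2-fold. With upper-quartile scaling, which moved the median log2 fold change of all genes from -0.03 to -0.12, the share of higher genes was 46.7% (713 higher, 814 lower) in place of 60.9%. Leaving out 1 library gave 549 to 1712 genes. The count moved by over 1.5 times without control replicate 1 (775), control replicate 2 (549), K-Ras-G12D replicate 1 (557) and K-Ras-G12D replicate 3 (852). The gene count was 2552 with DESeq2, and 431 with the male-specific transcripts as a covariate.

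The samples also differed in ways that the labels do not describe. Transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 146.6 to 161.9 CPM in 3 of the 4 control samples and in 1 of the 4 K-Ras-G12D samples, and to 0.62 to 1.84 CPM in the rest. Posterior Hox genes (Hoxa13, Hoxb13, Hoxd10, Hoxd11 and Hoxd13) were high where Hoxb3 and Hoxb5 to Hoxb9 were low, and a score of their difference ran from -3.11 to 2.62 log2 units in control and from -2.79 to 5.03 in K-Ras-G12D samples. Control replicate 4 and K-Ras-G12D replicates 1, 3 and 4 had positive scores. The group means of the score were -1.19 ± 2.63 and 1.19 ± 3.20 (SD, n = 4 each), a difference within the spread (exact permutation test, two-sided p = 0.343). These Hox genes were chosen after their values were seen. The first principal component, with 39.3% of the variance of the 500 most variable genes, separated the groups, with controls from -34.49 to -9.84 and K-Ras-G12D samples from 3.05 to 43.7. Within the groups it also varied with the Hox score. Control replicate 4 (score 2.62) lay at -9.84, K-Ras-G12D replicate 3 (5.03) at 43.7 and K-Ras-G12D replicate 2 (-2.79) at 3.05. Neighbouring samples did not all keep the order of the score. The component thus need not stand for genotype alone.

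**Figure D1:**
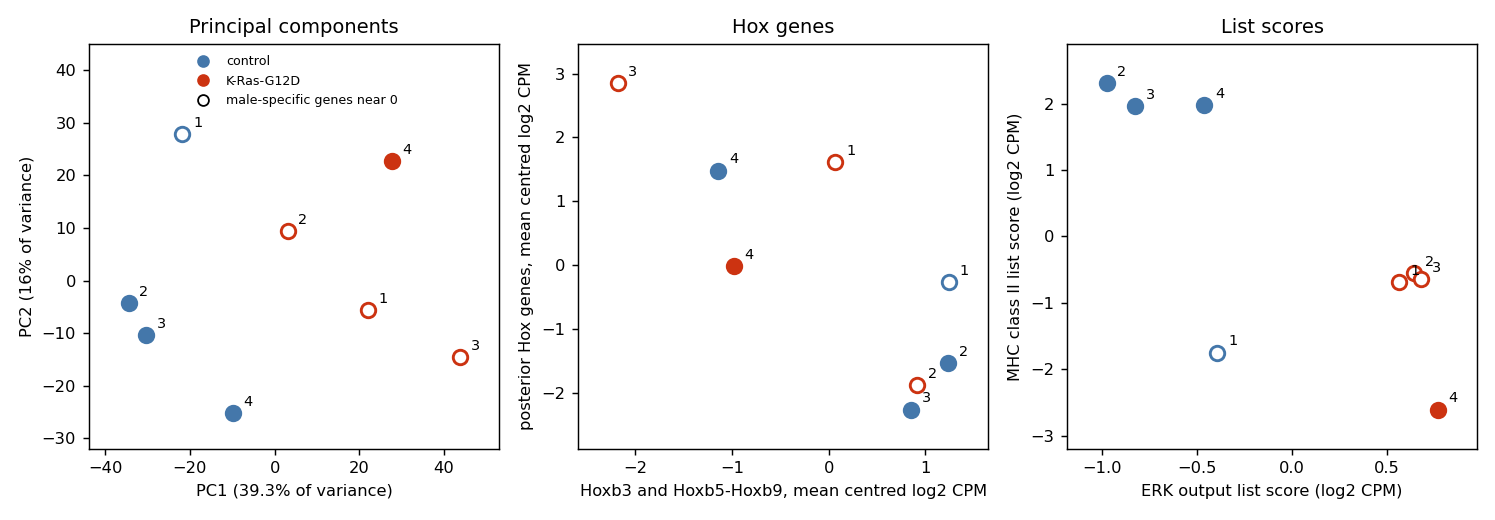
Each point is 1 sample, numbered by replicate, blue for control and red for K-Ras-G12D, and open where the male-specific transcripts were near 0. The left panel plots the first 2 principal components, with 39.3% and 16% of the variance; the middle panel plots the mean log2 CPM of the posterior Hox genes against that of Hoxb3 and Hoxb5 to Hoxb9, each gene centred on its mean; the right panel plots the MHC class II list score against the ERK output list score in log2 CPM. Control replicate 1 lies at -1.75 on the MHC class II score, apart from the other controls at 1.96 to 2.31.

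Among the 10 largest rises named by size were genes of transport and of cell contacts. The anion exchanger gene Slc26a7 had 2 counts in all 4 control samples together and 253 in the K-Ras-G12D samples, a ratio of 135 with a 95% exact counting interval of 36.9 to 1120. That interval leaves out the spread between samples, which was wide, with 13 to 160 counts per K-Ras-G12D sample (3.80 ± 3.85 CPM, SD, n = 4). Acot12, an acyl-CoA thioesterase (ENSMUSG00000021620, chromosome 13, 91741512 to 91786148), rose 66.5-fold, from 0.113 ± 0.094 to 8.28 ± 3.09 CPM (SD, n = 4 each, edgeR adjusted p = 0.00170). The serine protease Prss22 rose 44.3-fold, the transporter Slc4a11 30.4-fold, the adhesion molecule Cadm1 25.1-fold, the hyaluronan-binding protein Cemip 23.7-fold, Capn6 23.6-fold, the guidance molecule Sema3e 20.5-fold, the connexin Gjb4 17.9-fold and the apolipoprotein Apoc2 17.0-fold. Apoc2 reached 122.8 ± 52.9 CPM and was the most abundant of the 10 in K-Ras-G12D samples. Counts in control samples were low for most of them, with at most 9 per sample for Acot12, Prss22, Slc4a11, Cemip and Capn6. Of these, 3 calls were lost without 1 library, Cemip without control replicate 2 (edgeR adjusted p = 0.0551), Capn6 without K-Ras-G12D replicate 1 (0.0502) and Gjb4 without control replicate 1 (0.0517).

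The gene with the largest fall was Zfp654, a zinc finger gene (ENSMUSG00000047141, chromosome 16, 64780347 to 64851652, GRCm38). It had 64 to 114 counts in each control sample and 0 in every K-Ras-G12D sample, at least 99.5-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.00269). The secreted lectin Itln1 (chromosome 1, 171518122 to 171535294) fell 42.8-fold, from 19.2 ± 15.0 to 0.437 ± 0.356 CPM, and the pentraxin Mptx1 (chromosome 1, 174330518 to 174332873) fell 39.9-fold, from 633.2 ± 481.8 to 15.9 ± 9.09 CPM (SD, n = 4 each). Falls were 29.4-fold for the sterol transporter Abcg5, 26.5-fold for Nags, which makes the activator of the urea cycle, 24.3-fold for the calcium-binding protein S100g, 20.6-fold for the receptor kinase Ntrk2, 15.5-fold for the carboxylesterase Ces1g, 12.7-fold for Tmem252 and 10.3-fold for the glucuronosyltransferase Ugt2b5. Adjusted p lay at 0.0273 or lower for all 10 in the edgeR test. Ces1g and Ugt2b5 have close paralogs, among which the counting could divide reads. Without 1 library the calls of S100g, Ntrk2, Ces1g, Tmem252 and Ugt2b5 were lost, each without K-Ras-G12D replicate 1. S100g and Ntrk2 also lost theirs without control replicate 2, S100g without K-Ras-G12D replicate 3, and Ugt2b5 without control replicates 1, 2 and 3 and K-Ras-G12D replicates 3 and 4. The highest edgeR adjusted p among these fits was 0.0842.

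The ERK output list, made of target and feedback genes of the RAS-ERK pathway, had 12 of its 17 tested members higher, 1 lower and 4 not past the threshold. Adjusted over the list alone, 14 were higher and 1 lower. Its median log2 fold change was 1.42, and the list rose against all other genes (camera adjusted p = 1.753e-12), with an adjusted p of 0.0996 with an estimated correlation. Dusp4 (chromosome 8, 34807297 to 34819894) rose from 3.71 ± 1.19 to 35.9 ± 8.89 CPM, a log2 fold change of 3.27 ± 0.27 (SE, edgeR adjusted p = 0.00108). The interleukin-1 receptor antagonist Il1rn rose 8.12-fold, the feedback inhibitor Spry1 3.04-fold and the receptor kinase Epha2 2.93-fold. Ccnd1, the cyclin D1 gene, was the member that fell, 2.59-fold, from 105.6 ± 9.97 to 40.8 ± 17.0 CPM (edgeR adjusted p = 0.0174). It was chosen after its values were seen, and it lost its call without control replicate 2 or K-Ras-G12D replicate 1 (highest adjusted p 0.0559). The number of higher members was 7 without either of these 2 libraries, and 6 with the male-specific covariate, where the list still passed (camera adjusted p = 2.554e-12). The list score, the mean centred log2 CPM of the members, was -0.98 to -0.39 in controls and 0.57 to 0.77 in K-Ras-G12D samples.

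Of 15 immediate early genes, 3 were higher and none lower (4 higher adjusted over the list alone), all 15 had positive fold changes, and the list rose (median log2 fold change 0.55, camera adjusted p = 0.00111; adjusted p = 0.400 with an estimated correlation). The anti-proliferative gene Btg2 rose 2.73-fold and passed in all 8 fits that left out 1 library. The other 2, Junb and Egr1, passed in 2 of them each (highest edgeR adjusted p 0.0982 and 0.0856), and 1 gene of the list passed without control replicates 2 and 3 and K-Ras-G12D replicates 1, 3 and 4. Of 5 ligands of the EGF receptor family, Hbegf and Btc were higher in edgeR (3 adjusted over the list alone) and the list did not pass (camera adjusted p = 0.107), except without K-Ras-G12D replicate 1 (0.0490). Hbegf passed in 1 and Btc in 3 of the 8 fits (highest edgeR adjusted p 0.110 and 0.0773), and the count of ligands was 0 without control replicate 2 and K-Ras-G12D replicates 1 and 3 and 1 without each other library. Of 10 senescence and p53 targets, 2 were higher (3 adjusted over the list alone), Trp53inp1 1.67-fold and the cell cycle inhibitor Cdkn1a 1.99-fold, from 380.1 ± 67.2 to 758.2 ± 125.6 CPM, and the list did not pass (camera adjusted p = 0.0565), except without control replicate 2 (0.0486) and K-Ras-G12D replicates 1 (0.0445) and 3 (0.0491) and with the male-specific, stromal or Hox covariate (0.0456, 0.0388 and 0.0373). The YAP and fetal-like regenerative list rose (median log2 fold change 0.77, camera adjusted p = 0.0352; adjusted p = 0.502 with an estimated correlation), with 2 of 9 members, Anxa1 and Anxa3, higher in edgeR over all genes and adjusted over the list alone. The count was 0 without control replicates 1, 2 and 3 and K-Ras-G12D replicates 1 and 3, and 1 without K-Ras-G12D replicate 4, with a highest edgeR adjusted p of 0.0668 for Anxa1 and 0.104 for Anxa3. The list was lost without control replicate 3 or K-Ras-G12D replicate 3 (highest adjusted p 0.0654) and with the male-specific covariate (0.1001). The epithelial-mesenchymal transition and matrix list also rose, with a median of 0.62 and a camera adjusted p of 0.0446 (0.400 with an estimated correlation). Only 6 of its 18 genes were tested, Plaur, Lamc2, Mmp7, Itga2, Itga6 and Mmp14, so the rise cannot speak for the whole program. The urokinase receptor Plaur rose 2.98-fold and the laminin chain Lamc2 5.74-fold. The other changed member, the matrix protease Mmp7, which is made by Paneth cells, fell 7.02-fold (3 higher and 1 lower adjusted over the list alone). Mmp7 lost its call without control replicates 1, 2 and 3 and K-Ras-G12D replicates 1 and 4 (highest edgeR adjusted p 0.0936). This list passed in 4 of the 8 fits that left out 1 library and was lost without control replicates 1, 3 and 4 and K-Ras-G12D replicate 2 (highest adjusted p 0.0812), with limma-voom (0.0732) and with the authors' factors (0.0827).

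**Figure D2:**
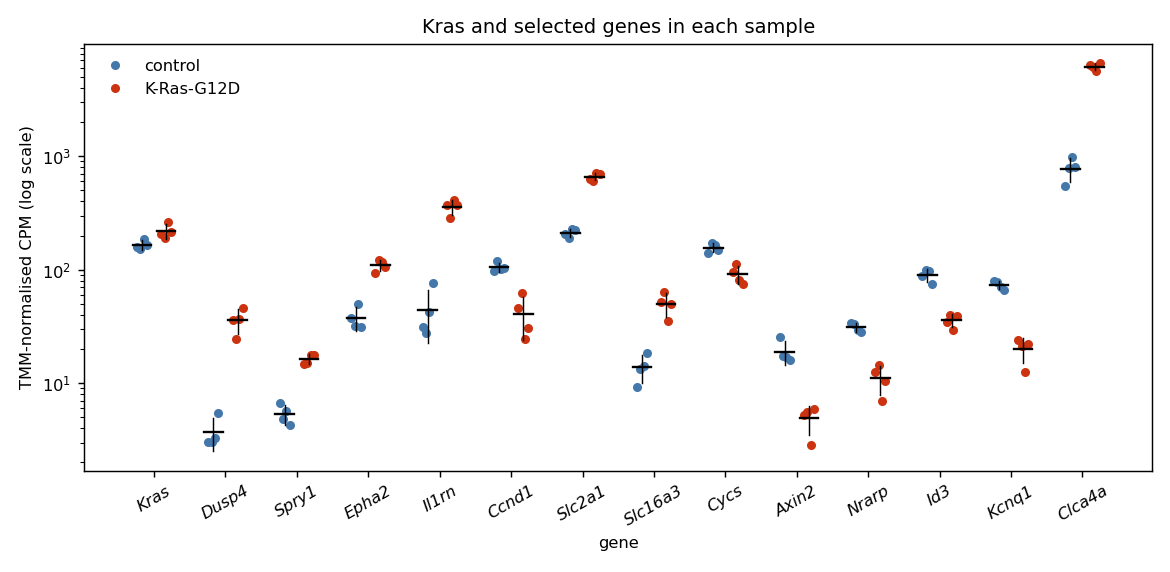
Normalised CPM on a log scale (y axis) of Kras and 13 genes named in the text (x axis). Each point is 1 sample, blue for control and red for K-Ras-G12D; horizontal bars are means and vertical bars 1 SD (n = 4 per group). Dusp4 lies at 3.71 ± 1.19 CPM in control and 35.9 ± 8.89 CPM in K-Ras-G12D samples, while Axin2 lies at 19.0 ± 4.48 and 4.90 ± 1.38 CPM.

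Genes of glycolysis and the hypoxia response moved one way, with 8 of 22 members higher, none lower, and positive fold changes in all 22 (11 higher adjusted over the list alone; median log2 fold change 0.48, camera adjusted p = 7.194e-08; adjusted p = 0.400 with an estimated correlation). Slc2a1 rose from 211.8 ± 16.6 to 661.3 ± 47.0 CPM, the lactate transporter Slc16a3 rose 3.63-fold, and the carbonic anhydrase Car9 1.59-fold. Oxidative phosphorylation moved the other way, with 7 of 21 members lower, none higher, and no positive fold change (11 lower adjusted over the list alone; median -0.37, camera adjusted p = 2.001e-05; adjusted p = 0.502 with an estimated correlation). Cytochrome c, Cycs, fell 1.71-fold, from 156.5 ± 14.2 to 91.4 ± 16.7 CPM. Without 1 library, 3 to 7 of the glycolysis genes passed, 3 without control replicate 2 or K-Ras-G12D replicate 1 and 4 without control replicate 1 or 3 or K-Ras-G12D replicate 3. Of the oxidative phosphorylation genes 1 to 10 passed, 1 without control replicate 1 or 2 or K-Ras-G12D replicate 1, 2 without control replicate 3 or 4 or K-Ras-G12D replicate 3, 3 without K-Ras-G12D replicate 4 and 10 without K-Ras-G12D replicate 2. With the male-specific covariate 4 glycolysis and 0 oxidative phosphorylation genes passed, while both lists did (camera adjusted p = 5.813e-08 and 0.00132). Of 18 genes of fatty acid oxidation and ketogenesis, 1 passed in edgeR, the peroxisomal enzyme Ehhadh, which fell 1.82-fold (1 adjusted over the list alone, 9 lower at an unadjusted p under 0.05, 5 in DESeq2; list median -0.35, camera adjusted p = 0.0194; adjusted p = 0.552 with an estimated correlation). Of 21 genes of cholesterol synthesis, 1 passed in edgeR, Insig1, the sterol-regulated inhibitor of the pathway, which rose 2.44-fold (1 adjusted over the list alone, 4 higher at an unadjusted p under 0.05, 3 in DESeq2; list median 0.22, camera adjusted p = 0.0162; adjusted p = 0.633 with an estimated correlation). The fatty acid list lost its call without control replicate 3 and with the Hox score as a covariate (adjusted p = 0.0596 and 0.0698), and the cholesterol list without control replicate 1 and with that covariate (0.0620 and 0.0674). Without control replicate 4, 3 fatty acid genes passed as lower and 3 cholesterol genes as higher, and without K-Ras-G12D replicate 2, 2 fatty acid genes. Of 18 ribosome biogenesis genes, none changed in edgeR, over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05 and 0 passed in DESeq2, with values of 1.10-fold for Ncl and 1.08-fold for Npm1 (camera adjusted p = 0.512). Of 16 unfolded protein response genes, 3 were lower (5 adjusted over the list alone; median -0.33, camera adjusted p = 0.0446; adjusted p = 0.502 with an estimated correlation), and the list lost its call without control replicates 3 and 4 and K-Ras-G12D replicates 2 and 4 (highest adjusted p 0.121), with the replicate block (0.0711) and with the authors' factors (0.0510). Its count of lower genes was 0 without control replicates 1 and 2 and K-Ras-G12D replicates 1, 3 and 4, and 1 without control replicate 4.

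All 24 tested proliferation genes had negative fold changes, with a median log2 of -0.67, and the list fell (camera adjusted p = 2.926e-06; adjusted p = 0.527 with an estimated correlation of 0.895 between its members). Only the mitotic kinase Aurka passed on its own in edgeR, 1.91-fold lower (0 adjusted over the list alone, 15 at an unadjusted p under 0.05, 7 in DESeq2). K-Ras-G12D replicate 2 lay among the controls on the list score (exact permutation test, two-sided p = 0.057), and without it 18 of the 24 genes passed as lower. Aurka lost its call in 7 of the 8 fits that left out 1 library, all but that without K-Ras-G12D replicate 2 (highest adjusted p 0.107). Of 13 stem cell genes, 4 were lower and 1, Prom1, was higher (7 and 1 adjusted over the list alone; median -0.63, camera adjusted p = 0.0446; adjusted p = 0.502 with an estimated correlation). The list passed in 4 of the 8 fits that left out 1 library and was lost without control replicates 1 and 4 and K-Ras-G12D replicates 1 and 2 (highest adjusted p 0.121), and also with upper-quartile factors (0.0713) and limma-voom (0.0846). In edgeR 1 gene of the list was lower without control replicates 1 and 2 and K-Ras-G12D replicates 1 and 4, and 2 without control replicate 4. Prom1, which marks stem and progenitor cells but is also made elsewhere in the crypt, rose 2.68-fold to 1278 ± 147.3 CPM. Axin2, a member of both the stem cell and Wnt target lists, was the 1 Wnt target of 8 to pass in edgeR over all genes (3 lower adjusted over the list alone, 4 at an unadjusted p under 0.05, 3 in DESeq2, 2 in limma-voom, and 2 in edgeR with upper-quartile factors or without K-Ras-G12D replicate 3). The Wnt list did not pass (camera adjusted p = 0.0744), except without control replicates 2 (0.0469) and 3 (0.0483) and K-Ras-G12D replicate 3 (0.0302), with the male-specific, stromal or Hox covariate (0.0225, 0.0457 and 0.0179) and with the authors' factors (0.0490). In the Notch list 2 of 8 genes were lower, over all genes and adjusted over the list alone, among them the Notch target Nrarp, 2.81-fold, from 31.2 ± 2.79 to 11.1 ± 3.22 CPM (camera adjusted p = 0.0565 for the list). The count was 1 without each library but control replicate 3, and the list passed without control replicates 2 (0.0447) and 3 (0.0227) and K-Ras-G12D replicates 1 (0.0445) and 3 (0.0409), and with the replicate block (0.0440) and the male-specific or Hox covariate (0.0193 and 0.0296). In the BMP list 2 of 9 were higher and 1, the BMP target Id3, was 2.5-fold lower, from 89.9 ± 11.2 to 35.9 ± 4.81 CPM (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.953 for the list). The count of higher BMP genes was 0 without control replicate 2 or K-Ras-G12D replicate 1 and 1 without control replicate 1 or K-Ras-G12D replicate 3 or 4.

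Deep crypt secretory and Paneth-cell genes had 3 of 8 members lower and none higher, and no positive fold change (4 lower adjusted over the list alone; median log2 fold change -1.91, camera adjusted p = 4.087e-04; adjusted p = 0.106 with an estimated correlation). Itln1 and Mptx1 were 2 of the 3. Genes of antimicrobial and barrier defence had 2 of 14 lower, over all genes and adjusted over the list alone (median -1.0, camera adjusted p = 0.0103; adjusted p = 0.502 with an estimated correlation), Itln1 and Retnlb, which fell from 494.9 ± 145.2 to 61.8 ± 42.2 CPM, and 4 were lower without K-Ras-G12D replicate 2. With limma-voom that list lost its call (0.0598). Enteroendocrine genes had 2 of 10 lower, among them the glucagon gene Gcg, 4.05-fold (4 adjusted over the list alone; median -0.76, camera adjusted p = 0.0334; adjusted p = 0.502 with an estimated correlation). Gcg lost its call without control replicates 1 and 2 and K-Ras-G12D replicate 1 (highest adjusted p 0.0686), and the enteroendocrine list without control replicate 1 and K-Ras-G12D replicate 2 (highest adjusted p 0.0768), and also with upper-quartile factors (0.0640) and limma-voom (0.0846). The count of lower enteroendocrine genes was 0 without control replicate 2 or K-Ras-G12D replicate 1, 1 without control replicate 1 or K-Ras-G12D replicate 3 or 4, and 4 without control replicate 4. Genes more typical of the small intestine had 4 of 8 lower and 1, the retinol-binding protein Rbp2, higher (6 and 1 adjusted over the list alone; median -2.06, camera adjusted p = 0.0119; adjusted p = 0.477 with an estimated correlation). The count of lower genes was 0 without K-Ras-G12D replicate 1, 1 without control replicates 1, 2 and 3, and 2 without K-Ras-G12D replicates 3 and 4. The ileal bile acid binding protein Fabp6 fell 4.72-fold and the peptidase Anpep 3.69-fold. Rbp2 was chosen after its values were seen and passed in 3 of the 8 fits that left out 1 library, those without control replicate 4 and K-Ras-G12D replicates 2 and 3. Fabp6 lost its call without K-Ras-G12D replicate 1 (edgeR adjusted p = 0.0539). Anpep passed in 2 of the 8 fits that left out 1 library, those without control replicate 4 and K-Ras-G12D replicate 2, and its fold change turned to 0.06 log2 units with the authors' factors per gene and sample as offsets. The Hox score also differed between samples, as given above, and with it as a covariate the 2 lists still passed (camera adjusted p = 1.646e-04 for the deep crypt list and 0.0110 for the small intestine list). With limma-voom the small intestine list lost its call (0.0954, 2 genes lower) and the deep crypt list passed (0.0166, 1 gene lower).

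MHC class II genes, which present antigen, had 2 of 8 members lower over all genes and 7 adjusted over the list alone, with a median log2 fold change of -2.83 (camera adjusted p = 0.00120; adjusted p = 0.502 with an estimated correlation of 0.939). The count of lower genes was 5 with upper-quartile factors, 7 with DESeq2, and 0 with limma-voom (7 at an unadjusted p under 0.05 in edgeR), the replicate block and the male-specific, stromal or Hox covariate. H2-Ab1 fell 7.27-fold and H2-DMa 6.97-fold, but each lost its call in 7 and 6 of the 8 fits that left out 1 library, H2-Ab1 in all but that without control replicate 1 and H2-DMa in all but those without control replicate 1 and K-Ras-G12D replicate 2 (highest edgeR adjusted p 0.115 and 0.105). Without control replicate 1, 7 of the 8 genes passed as lower. Control replicate 1 had a list score of -1.75, below 3 of the 4 K-Ras-G12D samples, and the groups were not separated by the score (exact permutation test, two-sided p = 0.114). The samples with the male-specific transcripts near 0 include control replicate 1 and these 3 K-Ras-G12D samples. With the male-specific covariate the list missed the threshold (camera adjusted p = 0.0901), at a median log2 fold change of -2.41 against -2.83 without it. No interferon response gene of 24 changed in edgeR, over all genes or adjusted over the list alone (1 higher and 1 lower at an unadjusted p under 0.05, 1 in DESeq2), with values of 0.822-fold for Irf1 and 1.21-fold for Oasl2 (camera adjusted p = 0.977), and the list turned to lower with the male-specific covariate (median -0.85, camera adjusted p = 0.00175). Without K-Ras-G12D replicate 4, which lay at -2.01 on the score of this list, it passed as higher with 2 genes higher (camera adjusted p = 9.948e-04). Of 8 chemokines and cytokines, 1 was higher and 1 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.645), and both passed only without control replicate 4 and without K-Ras-G12D replicate 2 among the 8 fits.

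Absorptive colonocyte genes changed in both directions, with 1 of 21 higher and 2 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.207, and 0.00539 with the Hox covariate, where 3 were higher), and 2 were higher without control replicate 4 and without K-Ras-G12D replicate 2. Clca4a, a chloride channel accessory gene of the surface epithelium, rose 7.94-fold, from 778.7 ± 180.6 to 6185 ± 406.4 CPM (edgeR adjusted p = 5.656e-04). Clca4a and Mptx1 have close paralogs, so their values are uncertain where the counting divided reads among copies. The sulfotransferase Sult1a1 fell 7.27-fold, from 213.8 ± 83.9 to 29.4 ± 6.47 CPM, and the guanylate cyclase ligand Guca2b fell 3.33-fold. Of 20 ion and water transport genes, 4 were lower and 0 higher in edgeR (4 lower and 3 higher adjusted over the list alone, 4 and 4 at an unadjusted p under 0.05, 4 lower and 5 higher in DESeq2). The count of lower genes was 1 without control replicates 1 and 2 and K-Ras-G12D replicate 1, and 2 without control replicate 4 and K-Ras-G12D replicates 3 and 4, and without K-Ras-G12D replicate 2 there were 3 lower and 3 higher. The potassium channel gene Kcnq1 fell 3.68-fold, from 73.7 ± 6.34 to 19.98 ± 5.05 CPM. The median of that list was -0.03, its mean was 0.32, and it did not pass (camera adjusted p = 0.597). Of 21 goblet cell genes, 2 were higher, among them Sytl2 at 3.38-fold, and 2 were lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.957). Without K-Ras-G12D replicate 2, 5 goblet genes were higher, and without each other library 1 was, while 1 was lower without control replicate 2 and without K-Ras-G12D replicate 1. None of 11 tuft cell genes passed in edgeR over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 or passed in DESeq2 (camera adjusted p = 0.878), with values of 1.04-fold for Trpm5 and 0.878-fold for Hck. In edgeR 1 tuft cell gene was higher without control replicate 4. Of 14 circadian clock genes 1 was lower, over all genes and adjusted over the list alone, the transcriptional repressor Nfil3 at 4.77-fold (camera adjusted p = 0.0896, and 0.0227 without control replicate 3). Nfil3 lost its call without control replicates 1 and 2 and K-Ras-G12D replicate 1 (highest edgeR adjusted p 0.0580).

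Of markers of other cells that a scraping can hold, none of 14 fibroblast, 5 smooth muscle, 4 endothelial, 11 macrophage and dendritic, 10 T and NK, and 11 B and plasma cell genes passed in edgeR, over all genes or adjusted over the lists alone, and camera adjusted p lay between 0.207 and 0.983 for these lists. At an unadjusted p under 0.05 there were 2 fibroblast genes and 2 smooth muscle genes, 0 in the other lists, and DESeq2 called 1 smooth muscle gene. Without control replicate 1 the B and plasma cell list passed as lower (camera adjusted p = 0.0366), and without K-Ras-G12D replicate 2 so did the fibroblast list (0.0386) and the T and NK cell list (0.0386), with 1 fibroblast and 1 macrophage gene lower. The fibroblast list also passed with the male-specific covariate (0.0191). The most abundant fibroblast gene, Col3a1, had a log2 fold change of -0.06 ± 0.41 (SE), the macrophage gene Ctss 0.41 ± 0.20 and the immunoglobulin gene Igha -1.0 ± 0.73. Mean and median had opposite signs in the endothelial list, at 0.07 and -0.17, and in the macrophage list both were above 0, at 0.02 and 0.04, where camera gave the direction as lower. Of 6 adipocyte genes 1 was lower, Car3, at 9.40-fold (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.290, and 0.0205 without control replicate 2). Lists with fewer than 4 tested genes were not tested as lists. Among their members the squamous keratin gene Krt13 rose 4.49-fold, the neutrophil gene Ly6g had a log2 fold change of 1.66 ± 1.01, the mast cell gene Mcpt1 of -0.22 ± 0.74 and the red cell gene Hbb-bs of 0.31 ± 0.49 (SE). The list of enteric neurons and glia had no gene in the table. Car3 and Krt13 lost their calls in 4 and 6 of the 8 fits that left out 1 library, both without control replicate 1 and K-Ras-G12D replicates 1 and 3, Car3 also without K-Ras-G12D replicate 4, and Krt13 also without control replicates 2, 3 and 4 (highest edgeR adjusted p 0.0814 and 0.12).

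**Figure D3:**
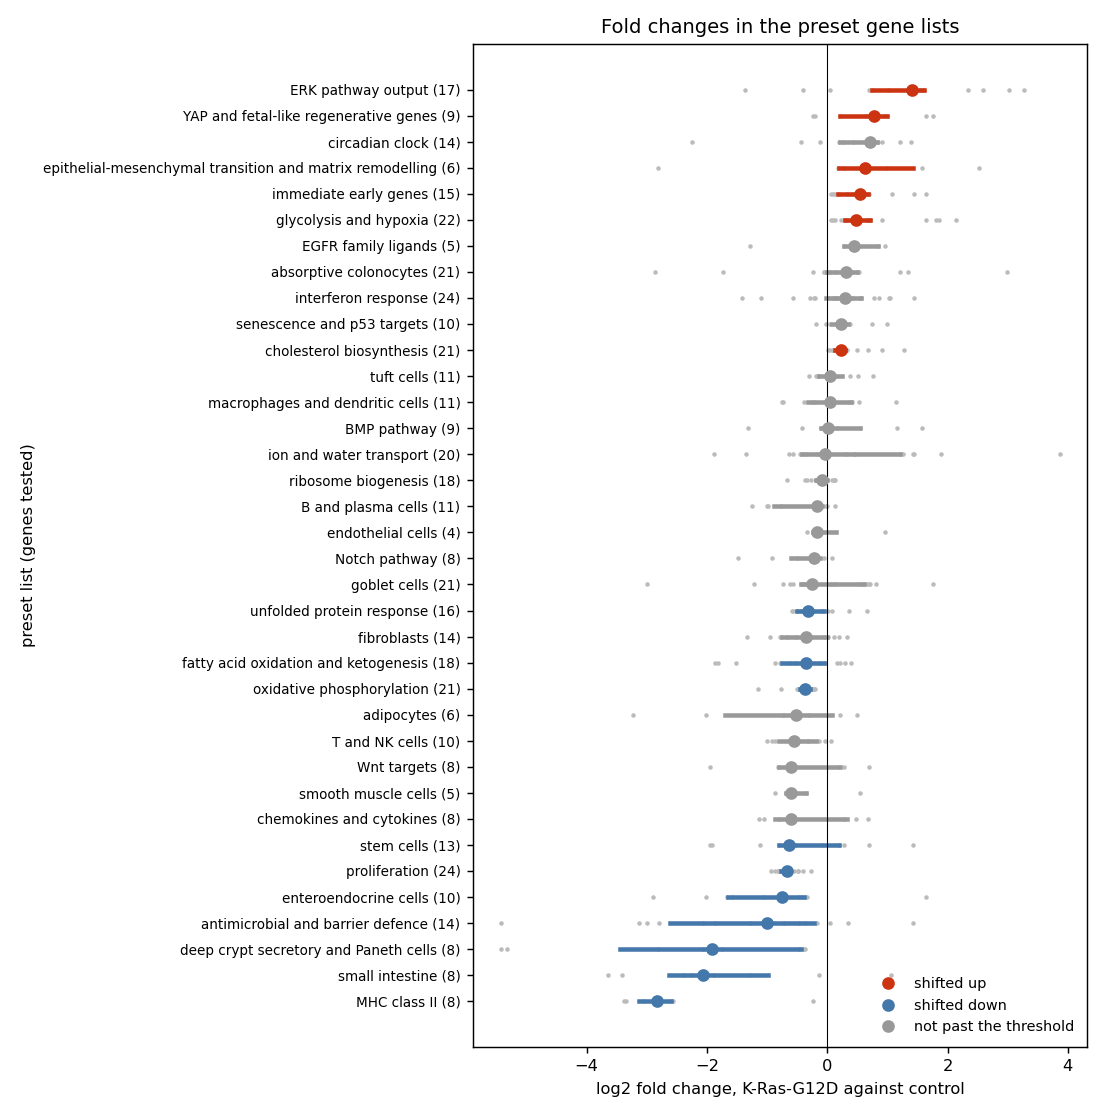
Log2 fold change of K-Ras-G12D against control (x axis) for the 36 preset lists with at least 4 tested genes (y axis, with the number of genes). Grey dots are genes, large points medians and thick lines the quartiles; red and blue mark the 6 lists shifted up and the 10 shifted down at a camera adjusted p of 0.05 or less with a preset correlation of 0.01. The medians run from -2.83 for MHC class II to 1.42 for ERK output.

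In all, 16 of the 36 lists shifted with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.0996. With the estimate, 3 lists had an unadjusted camera p under 0.05, those of ERK output, glycolysis and deep crypt cells. The fry test called 11 lists. The scores of the groups did not overlap in 10 of the 36 lists, where 1.03 are expected by chance, and 8 of these 10 were among the 16. Each of these 10 had an exact permutation p of 0.029, the smallest possible, and a Benjamini-Hochberg p of 0.104. Some lists share genes, such as Itln1, and all use the same samples, so the 10 are not independent results. Other splits of the 8 samples into 4 and 4 shifted up to 19 lists by camera.

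In the authors' deposited table, 1375 genes had an adjusted p of 0.05 or less, 912 higher and 463 lower in K-Ras-G12D. The edgeR calls shared 992 of them (72.1%), all with the same sign, and DESeq2 on the deposited counts shared 1208 (87.9%). All 20 genes named above by size passed in the authors' deposited table, which rests on the same samples. Their fold changes were smaller there, such as a log2 fold change of 3.25 for Slc26a7, against 6.69 in edgeR. Zfp654 was at -4.54, against -9.27 in edgeR, where 0 counts in K-Ras-G12D leave the size open beyond at least 99.5-fold. Whether the authors' fold changes were shrunk toward 0 is not given in the sources used here, so the sizes need not be alike in measure. In the authors' comparison, Kras had a log2 fold change of 0.52 and an adjusted p of 0.103.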

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

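The tests of sex, colon position and cell content below were chosen after the results were seen, and cell content was asked to hold in every fit after the values of the fits were seen, while the tests over other splits of the samples were planned.

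MHC class II list scores held an outlying sample in both groups. Control replicate 1 lay at -1.75 against 1.96 to 2.31 in the other controls (gap over range 0.914), and K-Ras-G12D replicate 4 lay at -2.61 against -0.69 to -0.55 (0.932). In control replicate 1, H2-DMa (0.831) and H2-Ab1 (0.82904) were low too, the latter barely past the critical value. In that sample the B and plasma cell score was -2.28, against 0.88 to 1.11 (0.932), and the tuft cell score was 0.67, against -0.37 to -0.21 (0.848). In K-Ras-G12D replicate 4 the interferon response score was -2.01, against 0.56 to 0.73 (0.937), and Oasl2 was at 5.20 log2 CPM, against 8.08 to 8.63 (0.841).

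The MHC class II list was lower in K-Ras-G12D, at a median log2 fold change of -2.83. For this, the tables argue against a lower content of macrophages as the whole cause. On the joint list of macrophages and dendritic cells the lowest marker, Fcer1g, was at -0.756. The 11 markers of that list are mostly macrophage genes, so a lower content of dendritic cells alone stays open. The markers lay above the MHC class II median by more than their spread in all 23 fits, which reuse the same samples. A lower content of B and plasma cells stays open: the lowest marker of their joint list, the plasma cell gene Jchain, was at -1.256. It lay beyond that spread in 22 of the 23 fits, not with the male-specific covariate, and the list passed as lower without control replicate 1 (camera adjusted p = 0.0366). The B cell genes Ms4a1, Cd79a and Pax5 were at -0.024 ± 0.947, -0.145 ± 0.860 and 0.129 ± 1.03 (SE), near 0 but too uncertain to decide. The samples low on the MHC class II list in each group were also the lowest on the B and plasma cell list, K-Ras-G12D replicate 4 at -1.38. Both were also lowest in their group on the macrophage and dendritic list. There control replicate 1 lay at -0.419, against 0.039 to 0.271 in the other controls. K-Ras-G12D replicate 4 lay at -0.576, against -0.097 to 0.383, so a part played by these cells stays open. Sex imbalance cannot be told apart from genotype for this list, since the difference of the list score was -1.84 ± 1.36 (SE) with the male-specific covariate and -2.25 ± 1.08 without it. Genotype stays open as a hypothesis, and no other biological explanation was tested.

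Other outlying samples lay within single genes or lists, where the gap over the range is given. In control replicate 4, Nags was low at 0.878, Ces1g low at 0.934, Dusp4 high at 0.851, Retnlb high at 0.891 and the fatty acid oxidation score low at 0.924. Axin2 was high in control replicate 1 at 0.862, Atp5o high in control replicate 2 at 0.895 and Spink4 low in control replicate 3 at 0.853. In K-Ras-G12D replicate 3, Ccl25 at 0.843, Cox7a2 at 0.875, Kcnq1 at 0.830 and Hck at 0.832 were low. Plaur was high in K-Ras-G12D replicate 4 at 0.851. In all 21 of 284 groups lay above the critical value, where chance gives about 5%, and control replicate 1 held 6 of them.

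As to the number of genes changed, chance alone was unlikely but not excluded. Of the 35 splits of the 8 samples, 1, the real one, gave 1490 genes, 907 higher and 583 lower, and the highest of the others gave 4. A share of 1 in 35 is the smallest that these splits can give. The other splits mix the genotypes within a group, which can raise the spread and lower their counts. The split with 4 genes follows the male-specific transcripts. The tables argue against sex imbalance as the whole cause, since that split gave 4 genes. With genotype in the model, 0 genes outside X and Y changed with the male-specific covariate. The fold changes of the 1490 genes kept a median of 0.992 of their size with that covariate (lower quartile 0.913). Only 420 stayed past the threshold, as the median SE grew from 0.156 to 0.188 while the median size of the log2 fold change went from 0.77 to 0.76. These genes were called for their difference by genotype, so this ratio could hardly fall far and decides nothing on its own. For position along the colon, the ratio with the Hox score as a covariate was 0.919 (lower quartile 0.835), and 982 genes stayed past the threshold. The same limit holds for this ratio, and 571 genes changed with the Hox score itself, so a part played by position stays open. For the number of shifted lists, chance cannot be excluded: 8 of the 35 splits shifted 16 lists or more, the highest of the others 19 with 0 genes called, which points to a structure of the samples in which genes of a list move together.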

How the results depend on the processing

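The settings with the authors' factors and with the Hox score were chosen after the data were seen, and the others were planned. All 1490 changed genes kept the sign of their fold change in every setting that gave them a value, except 6 with the authors' factors (1484 kept it). The number of genes changed, higher and lower was within 1.5 times of 1490, 907 and 583 with RLE and upper-quartile factors, limma-voom, both filters and the Hox score, and moved to 2552, 1495 and 1057 with DESeq2, 276, 197 and 79 with glmTreat, 431, 293 and 138 with the male-specific covariate, 728, 486 and 242 with the stromal covariate, and 592, 388 and 204 with the Hox and male-specific covariates. With DESeq2 and the authors' factors, 2320 genes changed and 1481 were higher, beyond 1.5 times, while the 839 lower stayed within it. With those factors in edgeR, 378 genes were lower. Covariates cost residual degrees of freedom, and glmTreat tests a larger change by construction; otherwise the cause was not tested. Without 1 library the ranges were 549 to 1712 changed, 382 to 980 higher and 156 to 732 lower, and fewer samples entered those fits. The log2 fold change of Kras ranged from 0.299 to 0.479 without 1 library, and it passed at 0.416 with DESeq2, at 0.461 without K-Ras-G12D replicate 2 and at 0.548 with DESeq2 and the authors' factors; the cause was not tested. The number of shifted lists was 0 with an estimated correlation, where the cause was not tested, and 11 to 20 in the other settings. Anpep turned to 0.064 in edgeR and 0.332 in DESeq2 with the authors' factors, and the interferon response list turned lower with the male-specific covariate (median -0.848) and with both covariates (-0.766); the cause was not tested. Of 36 lists, the Hox covariate lost 2 calls and added 4.

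Same-numbered samples did not deviate together, with correlations of -0.06, 0.38, -0.01 and -0.05, so the pairing was not used. With the replicate number as a block, 1279 genes changed, 1069 of them shared with the fit without it, 16 lists shifted and Kras passed at 0.395. Of the named genes, 20 lost their call with the block and 1 gained it. At these totals of 14255505 to 17795679 counts, depth limits genes with few counts, such as the 147 with 0 in some sample.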

Other observations

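The gene groups and tests below were chosen after the results were seen. Some annexin genes rose in K-Ras-G12D epithelium. Among 183 families of at least 8 genes that share a symbol stem, the Anxa family had 6 of 9 genes higher (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00394 over 366 tests), with Anxa8, Anxa2, Anxa5 and Anxa11 among them. Anxa8 rose by a log2 fold change of 3.69 and lost its edgeR call without control replicate 1 or 2 (highest adjusted p 0.0542). With the male-specific covariate 3 of the 9 passed, at a family median log2 fold change of 0.883 against 0.836 without it. Anxa1 and Anxa3 passed in 3 and 2 of the 8 fits that left out 1 library, neither without control replicates 1, 2 and 3 and K-Ras-G12D replicates 1 and 3, nor Anxa3 without K-Ras-G12D replicate 4 (highest edgeR adjusted p 0.0668 and 0.104). The Dusp family of dual-specificity phosphatases had 7 of 17 higher (adjusted p = 0.0183), and 3 higher with the male-specific covariate, at a median of 0.452 against 0.456, and it shares 3 of the 7, Dusp4, Dusp5 and Dusp6, with the ERK output list. Of the subunits of respiratory complex I, 9 of 11 Ndufb genes (adjusted p = 5.95e-08) and 5 of 12 Ndufa genes (0.0183) were lower, with negative medians under each scaling tried. These family tests count genes as independent, so their p-values are too small where members move together. The oxidative phosphorylation list, which holds Ndufb and Ndufa genes, had an estimated correlation of 0.732 and a camera adjusted p of 0.502 with it. Of 8 Ndufs genes 1 passed as lower (adjusted p = 1), at a family median of -0.473, beside -0.457 for Ndufb and -0.363 for Ndufa. Ndufb5 passed in 3 of the 8 fits and lost its call without control replicates 1, 2 and 4 and K-Ras-G12D replicates 1 and 3 (highest edgeR adjusted p 0.0842). With the Hox score as a covariate 4 Ndufb and 2 Ndufa genes passed, at medians of -0.363 and -0.272, and with the male-specific covariate 0 and 0 passed in edgeR, at medians of -0.394 and -0.341. The Slc family had 24 of 206 lower (0.0183) and 15 higher, but 14 lower and 17 higher with the authors' factors, 6 and 6 with the male-specific covariate, and 31 and 10 with upper-quartile factors.

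The gene with the smallest p, Sema7a, a membrane-anchored semaphorin, rose 10.1-fold, from 7.36 ± 1.03 to 74.2 ± 11.4 CPM (SD, n = 4 each, edgeR adjusted p = 1.245e-04). The laminin genes Lama3 and Lamb3 rose by log2 fold changes of 3.14 and 1.37, beside Lamc2 at 2.52. The claudin gene Cldn4 rose by 2.74 and Cldn2 fell by 2.29, the latter without a call when K-Ras-G12D replicate 1 was left out (adjusted p = 0.0503). The receptor genes Egfr and Erbb2 rose by 1.61 and 0.62 and the cystine transporter gene Slc7a11 by 3.22. These genes passed in edgeR in all 8 fits that left out 1 library, except Cldn2.

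Zfp654 was the only gene with at most 3 counts in every sample of one group and at least 20 in every sample of the other. Its neighbours Cggbp1 and 4930453N24Rik had log2 fold changes of 0.34 and 0.10 (edgeR adjusted p = 0.103 and 0.587). Within 5 Mb of Kras, 8 of 35 genes changed (22.9%, against 13.6% elsewhere; Fisher's exact test, two-sided p = 0.133, Benjamini-Hochberg 0.2 over 3 distances).

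Of the 16 genes of the small intestine and deep crypt lists, 7 were lower and Rbp2 higher. Over the 16 genes the fold change with the Hox score kept a median of 0.903 of its size (lower quartile 0.790) and with the male-specific covariate 1.079 (lower quartile 0.998). Only 5 and 3 of the 16 passed with them.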
